A study of Sus scrofa with 2 samples.

How the data were processed

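Whole-genome bisulfite sequencing was analysed in longissimus dorsi, the long back muscle, of 2 female Tibetan pigs. Bisulfite converts unmethylated cytosine so that it is read as thymine, whereas methylated cytosine is still read as cytosine, and the share of cytosine reads at a position gives its methylation level. Per the labels, the genomic DNA carried added lambda phage DNA, was sheared, ligated to methylated adapters, converted and sequenced on an Illumina instrument. Bismark 0.12.5 is named in the submitters' processing notes. The genome build, the read filters and the treatment of duplicate reads are not given in the sources used here.

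Each library came as a list of cytosines. Per the file headers, the deposited columns hold the counts of methylated and unmethylated reads at each cytosine, a methylation level given as a fraction, and a p-value with its corrected form. From the values, the deposited fraction equals the share of methylated reads after removal of a constant non-conversion rate, which was 0.0292% in the high-altitude library and 0.0277% in the low-altitude library. The deposited p-value equals the upper tail of a binomial distribution with that rate, within 0.1%, in 100% of 2089 lines checked in the high-altitude and 2021 in the low-altitude file. Every listed cytosine lies in a CpG, has at least 5 reads and at least 1 methylated read, and has a corrected p-value below 0.05. The deposited files used here thus hold cytosines that the authors had called methylated. A cytosine without a methylated call, or with fewer than 5 reads, is absent from a list, and these cases cannot be separated. A complete loss of methylation was therefore not measured, all levels refer to listed cytosines and leave out CpGs without methylated calls, and CHG and CHH levels were not analysed here.

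Methylation levels were computed from the read counts, as methylated reads over all reads, without the correction for non-conversion. Intervals are 95% Wilson intervals of the reads. No molecular identifiers are described and the treatment of duplicates is not given, so some reads may be copies of the same molecule. The intervals take reads as independent, cover counting error at most and may be too narrow. The median depth was 8 reads per listed cytosine in both libraries, and 34.5% and 33.2% of listed cytosines had at least 10 reads in the high- and the low-altitude library. All differences are low altitude minus high altitude, in percentage points. Mitochondrial cytosines were left out of all nuclear values and are given apart.

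For paired values, only cytosines listed in both libraries were used, and the strands of each CpG were summed. Single CpGs with at least 10 reads in each library were tested with the two-sided Fisher's exact test and Benjamini-Hochberg adjustment, and were called at an adjusted p below 0.05 and a difference of at least 25 points. Windows of 1 kb with at least 5 CpGs, each with at least 5 reads in each library, were tested in the same way on summed reads, with a difference of at least 20 points. With 1 pig per group, these tests compare 2 libraries and not 2 altitudes. Reads of neighbouring CpGs are not independent, so the p-values of windows are too small. As a measure of the calls that arise within a library, the same tests were run between the plus and the minus strand of each library. Levels of 1 Mb bins with at least 500 shared cytosines, of whole chromosomes and of classes of windows are means of site or window levels, with the SE over bins, sites or windows.

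The windows named in the report are the 4 with the largest rise and the 4 with the largest fall among called windows of at least 10 CpGs, a rule written before the data were examined. Bins, joined windows and other stretches that are named beside them were chosen after their values were seen. Positions are those of the files. They ran past the last gene of the gene table at hand, of assembly Sscrofa11.1, on 18 of 19 chromosomes, by up to 41.0 Mb, so that table belongs to another assembly. No gene, promoter or gene body value was computed for this reason.

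The calls were tested on simulated reads with the depths of these libraries. Of 50 windows lowered by 20 points, 4% were recovered. The recovered share was 32% at 30 points, 60% at 40 points and 86% at 50 points, and 3 of 462491 unchanged windows were called. These reads were drawn independently at each CpG, from a level shared by both libraries, and few windows were changed. The simulated shares are therefore not the error rates of the real tests. Between the strands of the high- and the low-altitude library, 43 and 29 of 19634 windows were called. When 200 of the 2588389 CpGs were changed, none of the 50 CpGs lowered by 60 points was recovered. With so few changed CpGs the adjustment was stricter than in the real data, where 8349 CpGs were called. This result therefore does not give the power of the real CpG test. Alternatives covered the depth minimum, the window size, the number of CpGs, the thresholds, an exact sign test over CpGs, thinning of the deeper library, removal of candidate sequence variants, removal of the deepest CpGs and subtraction of the median difference. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.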

Results

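DNA methylation was measured in longissimus dorsi muscle of 2 female Tibetan pigs. The first ranged freely on the Tibetan highland at an average altitude of 4000 m. The second was kept on ordinary feed on the Chengdu plain, at an average altitude of 500 m, and descended from Tibetan pigs bred in the lowland over several generations. Altitude, feeding, housing and descent thus differed together, and no pig was replicated. The high-altitude library listed 10441737 nuclear CpG cytosines with 99955761 reads, and the low-altitude library 10104425 with 95363149 reads. Both listed 7002043 of these cytosines, 67.1% of the high-altitude and 69.3% of the low-altitude list.

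The first comparison asked whether the methylome of muscle differed in level between the highland pig and its lowland counterpart, as the study's title concerns acclimation to low altitude. Muscle DNA of both pigs was highly methylated at the listed CpGs, and slightly less so in the low-altitude pig. Of all reads at listed cytosines, 71.46% were methylated in the high-altitude library (95% Wilson interval 71.45 to 71.47) and 70.55% in the low-altitude library (70.54 to 70.56), a difference of −0.91 points. At the cytosines listed in both libraries the mean site level was 73.5% and 72.4%, a difference of −1.07 points with an SD of 21.3 points over single sites. Cytosines were also grouped by depth where both libraries fell in the same class, which leaves out those with unlike depths. The mean difference was negative in each of 6 depth classes and ranged from −1.14 points at 5 to 6 reads to −0.31 points at 61 or more reads. In that deepest class, of 11236 cytosines, the level over reads was higher in the low-altitude pig, at 42.2% against 41.7%. Without a second pig per group, these differences have no replicate error.

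All 19 chromosomes had a lower mean site level in the low-altitude pig. The 18 autosomes had levels of 74.2% ± 0.84 (SD over autosomes) in the high-altitude pig and 73.2% ± 0.91 in the low-altitude pig, and their difference was −1.01 ± 0.18 points. Among autosomes it was smallest on chromosome 18, at −0.69 ± 0.12 points (SE over 61 bins of 1 Mb), and largest on chromosome 14, at −1.33 ± 0.086 points (SE over 154 bins). The X chromosome, of which female cells silence a copy, had the lowest mean site level in both pigs and the largest difference in mean site level. Its level was 61.9% in the high-altitude and 60.2% in the low-altitude pig, a difference of −1.73 ± 0.085 points (SE over 145 bins). Over reads instead of sites, chromosome 18 had a higher level in the low-altitude pig, with a difference of 0.74 points that was 0.043 points without cytosines deeper than 200 reads, and the other 18 chromosomes a lower level. Over reads the largest difference was on chromosome 10, at −1.88 points, against −1.65 points on X.

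**Figure D1:**
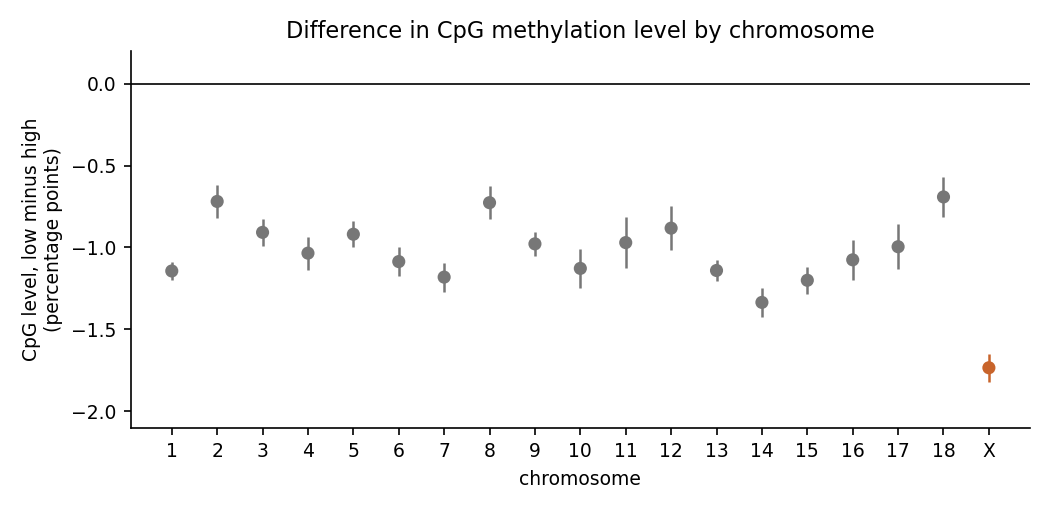
Difference in mean CpG methylation level, low minus high altitude, in percentage points, for each chromosome; points are means over cytosines listed in both libraries and bars are ± SE over 1 Mb bins. All chromosomes lie below 0, the autosomes between −0.69 and −1.33 points and X, in orange, at −1.73 points.

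Windows of intermediate methylation were more frequent on X among windows with 5 to 9 and with 10 to 19 listed CpGs. Among 1 kb windows with 5 to 9 CpGs, 35.4% of those on X and 10.8% of those on autosomes had a level of 40 to 60%, while 7.36% on X and 38.6% on autosomes were above 80%. With 10 to 19 CpGs, 17.8% of 3410 windows on X and 5.91% of 48523 on autosomes had a level of 40 to 60%. Above 80% were 10% on X and 46.2% on autosomes. On autosomes the mean difference between the pigs was largest in windows at 70 to 80%, at −1.17 ± 0.025 points (SE, 132690 windows). It was smaller in windows above 90%, at −0.45 ± 0.031 points, and in windows below 40%, at −0.32 ± 0.12 points, where the median difference was −0.90 points. Windows on X had a larger difference than autosomal windows in each level class, from −1.21 ± 0.45 points above 90% to −2.03 ± 0.11 points at 60 to 70%. Windows with at least 20 CpGs listed in both libraries had mean levels of 71.4% and 70.2% on autosomes, in 1445 windows. On X they had 74.0% and 71.3%, in 64 windows. CpGs without methylated calls are not listed, so the number of listed CpGs is not the CpG density of the sequence. Of these windows with at least 20 listed CpGs, 7.81% on X and 9.41% on autosomes had a level of 40 to 60%. The few windows on X do not allow a comparison.

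**Figure D2:**
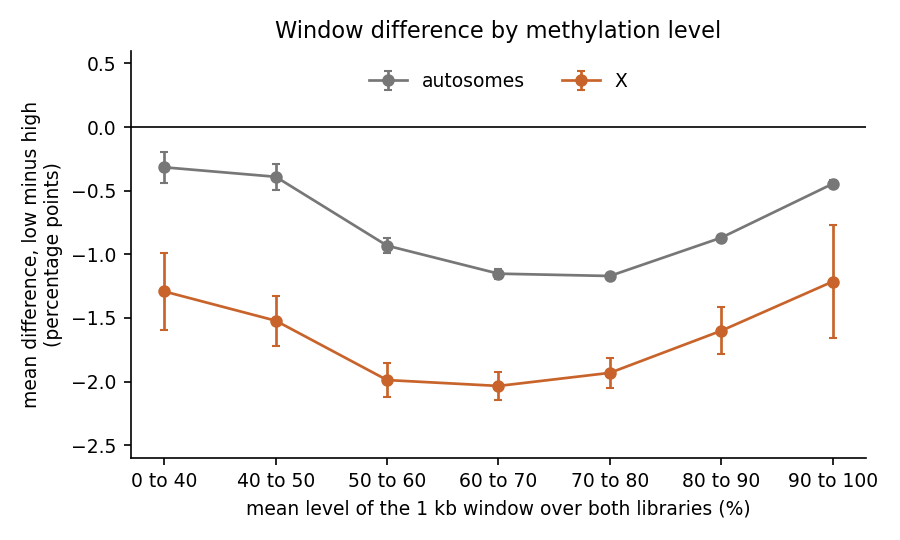
Mean difference of 1 kb windows, low minus high altitude, in percentage points, by the mean level of the window over both libraries in percent, for autosomes (grey) and X (orange); bars are ± SE over windows. X lies below the autosomes in each class, at −2.03 against −1.15 points in windows at 60 to 70%.

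Along the chromosomes the level of 1 Mb bins was close in both pigs, with a correlation of 0.988 across 2599 bins, which are not independent replicates. Of these bins, 2233 (85.9%) were lower in the low-altitude pig, among them 134 of 145 bins on X. A few regions stood apart from the mean difference. The bin from 67000001 to 68000000 on chromosome 16 had 68.1% and 62.6%, a difference of −5.49 ± 0.45 points (SE over 2583 cytosines), and the bin from 28000001 to 29000000 on chromosome 7 had 53.0% and 47.7%, −5.25 ± 0.68 points. In the opposite direction, the bin from 52000001 to 53000000 on chromosome 4 had 50.2% and 56.8%, a difference of 6.65 ± 0.53 points. The first Mb of chromosome 6 had 48.3% and 54.5%, a difference of 6.14 ± 0.21 points over 5734 cytosines, and the bin from 38000001 to 39000000 on chromosome 11 had 42.1% and 48.0%, 5.94 ± 0.75 points. These bins were chosen after their values were seen.

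The second comparison asked which regions differed between the 2 libraries. Of 462691 windows of 1 kb, 2286 (0.494%) were called by the Fisher's exact test, of which 1416 were lower and 870 higher in the low-altitude pig. On X, 73 of 91 called windows (80.2%) were lower, against 1304 of 2128 (61.3%) on autosomes, and this contrast of shares was not tested. The median difference over all windows was −1.01 points, with a correlation of the levels of both pigs of 0.774 across windows. The tested windows held a median of 6 CpGs, with a median of 75 reads in the high-altitude and 73 in the low-altitude library. The differences of separate windows had a correlation across windows of 0.060 at a distance of 1 kb, 0.022 at 10 kb and 0.0044 at 500 kb. In the smaller set of windows that could be split by strand, with 805 pairs at 10 kb, it was 0.101 and 0.11 between the pigs on the same strand at that distance, 0.0625 and 0.0824 on opposite strands, and 0.0211 and −0.0267 between the strands of the high- and the low-altitude library. At 1 kb, with 1296 pairs, it was 0.0964 and 0.105 between the pigs on the same strand and 0.0999 and 0.0981 on opposite strands. Between the strands of the high- and the low-altitude library it was −0.0349 and 0.0833 at 1 kb. At 100 kb, with 286 pairs, it ran from −0.0503 to 0.165 between the pigs, and was −0.00101 and 0.0476 between the strands. Counting error of single windows lowers these correlations, so they do not give the extent of a difference. The number of called windows was 1055 when CpGs needed at least 10 reads and 894 at a difference of at least 30 points. It was 379 when only windows with at least 10 CpGs were tested and adjusted, and 2 by an exact sign test over the CpGs of a window.

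Calls within a library were read from its strands, which share the DNA, conversion and amplification and so leave out differences between preparations. In 19634 windows that could be split, 43 were called between the strands of the high-altitude library and 29 between those of the low-altitude library. Between the pigs on opposite strands, 178 and 141 of the same windows were called, and on the same strand 67 and 81. The fewer calls on the same strand show that part of the strand difference recurred in both pigs. Calls between strands therefore hold more than noise.

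Under the adjustment over all 462691 windows, 289 called windows held at least 10 CpGs. Among these 289, the 4 with the largest loss in the low-altitude pig were methylated in most reads of the high-altitude pig. The largest was on chromosome 12, from 9034001 to 9035000, with 82.4% (84 of 102 reads) at high and 43.8% (35 of 80 reads) at low altitude over 10 CpGs, a difference of −38.6 points (Fisher's exact test, adjusted p = 0.000156). The only tested window within 3 kb of it differed in the opposite direction, with 44.1% and 60.3%. On chromosome 14, from 149588001 to 149589000, the level was 88.0% (117 reads) and 51.4% (72 reads), while 5 windows within 3 kb had mean levels of 85.1% and 76.5%. On chromosome 4, from 54233001 to 54234000, it was 86.5% (156 reads) and 50% (146 reads) over 16 CpGs (adjusted p of the exact test 5.62e-08). On chromosome 10, from 34478001 to 34479000, it was 78.1% (114 reads) and 41.5% (130 reads). This window was not called when only its 5 CpGs with at least 10 reads were used, with a difference of −28.0 points (adjusted p of the exact test 0.059).

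The 4 windows with the largest gain in the low-altitude pig had low to intermediate levels in the high-altitude pig. On chromosome 8, from 141795001 to 141796000, the level was 35.1% (27 of 77 reads) at high and 75.7% (78 of 103 reads) at low altitude over 12 CpGs, a difference of 40.7 points (Fisher's exact test, adjusted p = 0.000144). The 3 tested windows within 3 kb of it had mean levels of 84.3% and 83.0%. On chromosome 15, from 7981001 to 7982000, the level was 26.1% (92 reads) and 63.4% (93 reads), with 70.2% and 67.3% in 4 neighbouring windows. On chromosome 11, from 86437001 to 86438000, it was 29.3% (147 reads) and 64.3% (143 reads) over 15 CpGs, with 56.1% and 65.4% in 2 neighbouring windows. On chromosome 13, from 147844001 to 147845000, it was 35.8% and 72.3%, with unequal depth of 288 and 83 reads, and its tested neighbour had 67.1% and 80.7%.

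**Figure D3:**
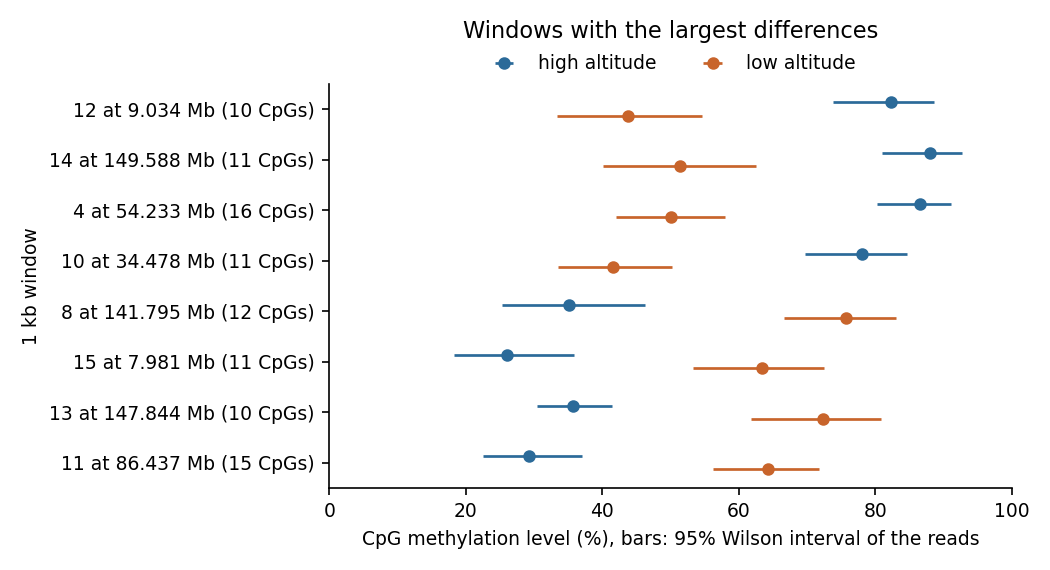
CpG methylation level in percent of the 4 windows of 1 kb with the largest loss and the 4 with the largest gain in the low-altitude pig, in the high-altitude (blue) and low-altitude (orange) library; bars are 95% Wilson intervals of the reads, and labels give chromosome, start and number of CpGs. The windows were selected for their difference, which was largest on chromosome 8, at 35.1% and 75.7%.

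Some called windows lay side by side. Joined across gaps of up to 1 kb, 40 of the 2286 called windows (1.75%) formed 20 regions of 2 windows each, 14 lower and 6 higher in the low-altitude pig. Not all neighbouring windows could be tested, so this share does not show how far a difference extended. Of these regions, chosen after their values were seen, the largest loss was on chromosome 11, from 66909001 to 66911000, with 82.3% (141 reads) and 45.2% (135 reads). On X, the region from 139629001 to 139632000 had 84.3% (248 reads) and 54.8% (228 reads), and that from 3574001 to 3577000 had 90.5% (169 reads) and 62.6% (147 reads). The largest gain was on chromosome 9, from 12350001 to 12352000, with 59.5% (126 reads) and 86.2% (152 reads). On chromosome 13, from 147807001 to 147809000, the level was 51.4% (539 reads) and 76.5% (353 reads), which lay close to the window of gain on that chromosome and also had more reads in the high-altitude library.

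At single CpGs, 8349 of 2588389 (0.323%) were called by the Fisher's exact test. Of these, 4563 (54.7%) were lower and 3786 higher in the low-altitude pig, and the median size of the difference was 62.9 points. Called CpGs had a median level of 93.8% in the higher and 28.6% in the lower library. The called share was 0.0740% on X (103 of 139156 CpGs), and on autosomes it ran from 0.277% on chromosome 1 to 0.410% on chromosome 10. Between the strands of a library, 178 of 250650 CpGs were called in the high-altitude and 163 of 188849 in the low-altitude pig. Between the pigs on opposite strands 509 of 217421 and 474 of 216842 were called, and on the same strand 399 of 328601 and 400 of 328297. The number of called CpGs was 4496 when CpGs with at least 5 reads entered the test and 4807 when each cytosine was tested alone.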

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

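Tests of the lower level in the low-altitude library, the larger difference on X and noise within a library were chosen after seeing the results. So were the levels of called and of deeper CpGs and the split of the mitochondrial calls. The tests of the level and depth of X and of sequence variants at called CpGs were written before their values were computed.

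The mean CpG level was about 1 point lower in the low-altitude library. Read depth does not account for it, since cytosines with equal reads in both libraries differed by −1.10 ± 0.024 points (SE, 920822 cytosines). These cytosines were listed in both libraries, so the test cannot tell what CpGs missing from a list would add. Incomplete conversion acts on the unmethylated share, which was 4.41 times as high in autosomal windows below 40% as in those at 80 to 90%, but the ratio of their differences was 0.364 ± 0.14 (SE) by mean and 1.03 ± 0.135 by median, and the rates behind the deposited levels, whose origin is not given in the sources used here, differed by 0.0016 points. A uniform loss of methylated calls would lower windows above 90% at least as much as those at 70 to 80%, but the ratio of the autosomal differences was 0.381 ± 0.028. Altitude, feeding, housing, descent, the individual pig and the makeup of the muscle sample remain open, were not tested and may each contribute. The same holds for library preparation, sequencing, mapping and duplicate reads, which cannot be told apart from the pig because each pig gave a single library.

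The difference in mean site level was larger on X than on each autosome, whereas over reads chromosome 10 (−1.88 points) exceeded X (−1.65 points). Standardised to the level classes of X, windows on X differed by −0.91 points more than autosomal windows (95% interval −1.07 to −0.756, resampling of 1 Mb blocks), so the lower level of X does not account for it. At cytosines of equal depth the excess was −0.825 points (−1.11 to −0.546), which argues against read depth. CpGs missing from a list were not part of this test. These intervals describe the spread along the genome of 2 libraries, and a difference between the pigs in the methylation of the inactive X copy is a candidate explanation that was not tested.

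Single CpGs were called less often on X. The 103 calls on X were 0.143 of the 720 expected from autosomal CpGs of the same level and depth class (95% Poisson interval 668 to 773). Without matching, the called share on X was 0.219 of the autosomal share. The class used the level pooled over both libraries, which a called difference itself shifts, so the comparison cannot exclude the level of X. Of called CpGs, 68.6% had at least 90% in the higher library. In the high-altitude library, 2.53% of cytosines on X and 9.21% on autosomes were at 100%, among those with at least 10 reads in both libraries. Calls between strands of a library were 0.348 times as frequent as calls between pigs on opposite strands, and 0.647 times as frequent as those on the same strand. Strand differences that recur in both pigs enter the calls between strands but not those on the same strand, so how much noise adds remains open. CpGs within 100 bp of 5120 called CpGs differed by 5.77 ± 0.24 points (SE) in the direction of the call, which is consistent with sequence variants at a part of them, although methylation that differs at an isolated CpG would look alike. The filter for candidate variants left in place levels of 20 to 40%, part of those below 20%, and all CpGs below 90% in the higher library. Without the candidates it removed, 6615 CpGs were called. The lower level of called CpGs was 40 to 60%, near that of a heterozygous variant, at 16.5%, 20 to 40% at 56.6% and at most 20% at 26.8%. A call needs a large difference, which favours CpGs sampled at a low level, so these values do not give the share of variants. Deeper CpGs, called or not, had at least 25 and below 60 reads in each library and at least 90% in the higher library. Of 46363 such CpGs, the lower library had 7 at 0 to 10%, 8 at 10 to 20%, 49 at 20 to 30% and 298 at 30 to 40%. It had 499 at 40 to 50%, 442 at 50 to 60% and 951 at 60 to 70%. The counts thus had a small local peak at 40 to 50%, and CpGs without methylated calls are not among them. Both explanations remain open.

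Methylated calls were also listed on the mitochondrial genome, which lies outside the nuclear comparison. The high-altitude library listed 93 mitochondrial cytosines with a level of 0.220% (429 of 195201 reads), and the low-altitude library listed 200 with a level of 0.508% (1364 of 268287 reads). A cytosine is listed only where it exceeds the non-conversion rate, so these levels were bound to lie above that rate and leave out all other mitochondrial cytosines. The contrast rested in large part on the minus strand between positions 3526 and 3736, without which the levels were 0.201% (344 of 171296 reads) and 0.299% (759 of 254151 reads). Reads from nuclear copies of mitochondrial sequence were not separated.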

How the results depend on the processing

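Tests added after the data were seen were those on cytosines listed in both libraries, at equal depth, without cytosines deeper than 200 reads, without X, the count of chromosomes by mean site level and over reads, and the named windows without candidate variants. No named window, median or share changed direction. The level difference, −0.91 points over all listed cytosines, was −1.05 as a mean over CpGs with at least 10 reads, −0.928 at cytosines listed in both libraries (all of which have at least 5 reads), −0.877 on autosomes, −1.10 at equal depth and −0.98 without cytosines deeper than 200 reads. The median window difference, −1.01 points, was −0.973 in windows of 500 bp, −1.04 in windows of 5 kb, −1.04 with at least 10 reads per CpG and −0.966 without X. These values lay outside the 95% interval of the main value, which was −1.039 to −0.982 points for the median. The error of the alternatives, some of them on fewer windows, was not computed. The values without X leave out a chromosome with a larger difference. Without cytosines deeper than 200 reads, sites at 41.6% in the high- and 42.2% in the low-altitude library are left out. The cause of the other shifts was not tested. The 2286 called windows became 1055 with at least 10 reads per CpG (106566 windows tested), 894 at 30 points, 379 among windows of at least 10 CpGs (55464 tested) and 2 by the exact sign test over CpGs in 129273 windows of at least 8 CpGs, where windows with few CpGs cannot reach a small p. The other 5 alternatives gave 1616 to 2244 windows. The 8349 called CpGs became 4496 when CpGs with at least 5 reads were tested (5988704 tests) and 4807 when each cytosine was tested alone, and the other 7 gave 5963 to 8442. The share of called CpGs that were lower was 53.0% with at least 20 reads, against 54.7%, and the cause was not tested. Reads-weighted levels were lower on 18 of 19 chromosomes, with and without cytosines deeper than 200 reads. The exception was chromosome 18, at 0.74 and 0.043 points, chromosome 16 moved from −0.034 to −1.04 points, and chromosome 10 had the largest difference over reads, at −1.88 and −1.84 points, against −1.65 points on X in both. Of 10 values of named windows under alternatives, 9 kept their call, and 6 of the 8 windows had too few CpGs with at least 10 reads for a value. Each window had a value without candidate variants, but this filter left several windows unchanged, so their calls were bound to stay. With at least 10 reads per CpG, the window on chromosome 11 kept its call, and the window on chromosome 10 did not. CHG and CHH levels, promoters, gene bodies and gene lists, with their alternatives, were not run. No paired analysis was possible because each group held 1 pig.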

Other observations

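The stretches and sites in this part were chosen after their values were seen, and no explanation was tested for them.

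A stretch of the mitochondrial genome carried more methylated calls in the low-altitude library, on the minus strand alone to this extent. Between positions 3526 and 3736, the 11 minus-strand cytosines listed there had a level of 4.28% (605 of 14136 reads, 95% Wilson interval 3.96 to 4.63), and single sites ran from 2.08% to 5.86%. The plus strand of the same stretch had 0.509% (62 of 12191 reads). In the high-altitude library the minus strand had 0.356% (85 of 23905 reads over 12 listed cytosines). Over the 43 mitochondrial cytosines listed in both libraries the level was 0.259% in the high-altitude and 1.42% in the low-altitude library, and 36 of them were higher in the latter. Reads from nuclear copies of mitochondrial sequence, where aligned there, were not separated, so these are shares of the aligned reads and not levels of mitochondrial DNA.

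Some stretches were listed in a single library. Runs of at least 3 adjacent 1 kb windows, each with at least 5 cytosines listed in one library and none in the other, numbered 24 for the high-altitude library (82 kb in all) and 23 for the low-altitude library (81 kb). The longest was on chromosome 2, from 160868001 to 160876000, with 60 cytosines at 58.3% in the high-altitude library. On chromosome 4, from 10931001 to 10938000, the low-altitude library listed 117 cytosines at 76.9%. A lack of listed cytosines can mean low depth, deleted sequence or unmethylated CpGs, which these lists do not separate.

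The difference that single called CpGs shared with their surroundings declined with distance. CpGs within 20 bp of a called CpG differed by 9.48 ± 0.45 points (SE, 1924 called CpGs) in its direction, those at 21 to 50 bp by 5.83 ± 0.39 points and those beyond 500 and up to 1000 bp by 1.74 ± 0.16 points.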
